A study of Mus musculus with 9 samples.

How the data were processed

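RNA was measured in the left ventricle of mice of the outbred ICR/CD1 strain at postnatal day 14. In transverse aortic constriction (TAC) a ligature narrows the aortic arch, so that the left ventricle pumps against a higher pressure. Per the labels, 3 libraries came from TAC at postnatal day 1 (day-1 TAC), 3 from TAC at postnatal day 7 (day-7 TAC) and 3 from sham-operated mice, for which the labels used here give no day of surgery. Messenger RNA was purified from total RNA with Dynabeads mRNA DIRECT, libraries were made with ScriptSeq v2, and single-end reads of 50 cycles were sequenced, per the labels' protocols.

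Trim Galore, STAR, edgeR and the mouse build mm10 are named in the submitters' processing notes. Their versions, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited values are log2 values, named as TMM-scaled in the file header, for 16710 rows of gene symbols and 9 libraries. In every library 100.0% of the values, taken out of the log, were whole multiples of a single step within a tolerance of 0.001 reads. Reads per gene were recovered with the lowest value of each library taken as 1 read. A pseudocount of 1 read cannot be told from none in this way, and with it each recovered number would be 1 too high. Recovered reads were between 18538900 and 26529531 per library. The library medians differed by at most 0.0026, so the deposited scale made the medians equal. Scaling the recovered reads by a trimmed mean moved no library by more than 0.036 on the log2 scale. With the lowest value taken as 1 read, no gene could come out without reads. If no pseudocount was added, a gene without reads in even 1 library was not analysed here, and a gene silent in 1 group is missed.

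In the table, 3 symbols stood on 4 rows each, in which 2 sets of sham and day-7 TAC values were crossed with 2 sets of day-1 TAC values. These 12 rows were left out, which kept 16698 genes. A join of the day-1 TAC columns to the others by symbol would give such a crossing. In the file header 2 sham columns carry the same name. Both belong to the sham group, and their numbers 2 and 3 here follow column order and pair nothing.

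Genes above 0 on the deposited log2 scale in at least 3 libraries were tested, which left 13712. limma 3.58.1 in R 4.3.3 was fitted to the log2 values of all 9 libraries in a single linear model with an intensity trend, since the values are not counts. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A fold change is the difference of group means of the deposited log2 values, given with its standard error (SE). Group values are the mean ± SD with n = 3. The labels do not say whether the samples of a group came from separate animals or litters, so p-values measure the spread between these samples. Differences among all groups were tested with limma's F test.

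Before the data were examined, 35 gene lists were fixed, of which 33 had enough tested members. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera was also run with the correlation estimated from the data, which called 0 of 33 lists in each comparison, with 4, 2 and 2 at an unadjusted p under 0.05; the lowest adjusted p was then 0.155 for day-1 TAC against sham, 0.0585 for day-7 TAC against sham and 0.424 between the TAC groups. On ranks it called 14, 12 and 12 lists. The genes named were set by a rule fixed at the same time: in each comparison, among called genes with a mean of at least 2 on the log2 scale and no overlap between the groups, the 10 largest rises and the 10 largest falls, without gene models that lack a name. Also named were up to 4 members with the smallest p of each list described, and 12 genes reported whatever their result. A few genes that this rule gave are not described here, for reasons other than their values. Which lists were described by their members, and which only by their counts, was decided after their results were known.

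Sham libraries are shared by both TAC comparisons, so the correlation of their fold changes was set beside 100 simulations without any effect. Gene coordinates are from GENCODE mouse release 21 on GRCm38 (mm10), in which 16401 symbols were found and 297 were not. Reads recovered for overlapping, antisense or near-identical genes, such as the myosin genes Myh6 and Myh7 or the actin genes, cannot be told apart with certainty. Within-group pairs of libraries differed by chi-square values of 10.3 to 30.2 per gene, above sampling noise, so none was a copy of another.

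The steps were tested on counts simulated from the real means and library sizes with 200 changed genes, each with a mean of at least 2 on the log2 scale. Genes were drawn independently and few were changed, so the rates that follow are not error rates of the real calls. For day-1 TAC against sham, over 13549 genes, 67.2% of 1.5-fold, 91.0% of 2.0-fold and 100% of 4.0-fold changes were recovered, with 8 false calls.

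Alternatives fixed before the data were examined for the gene counts were filters, quantile normalization, median centring, pseudocounts of 1 and 0.1, other variance models, library weights, a minimum fold change of 1.2, the replicate number as a block, 2-group fits and leaving out each library. Trimmed-mean and median-ratio scaling, voom weights on recovered reads, leaving out genes on chromosomes X and Y, a correction for GC content and length and camera under other filters and scalings were added after the data were seen. A count model was planned only for raw counts and was not run. Simulations were run in R. Reading of the values, some of the tables and the plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.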

Results

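Messenger RNA of the left ventricle was profiled in 9 libraries from mice at postnatal day 14, in groups of 3: sham surgery, TAC at day 7 and TAC at day 1. Recovered depth was 21112242, 26529531 and 19639428 reads in the sham libraries, 23926701, 19354619 and 20718699 with day-7 TAC, and 20144709, 19972581 and 18538900 with day-1 TAC. The first principal component held 50% of the variance and parted sham from TAC, and the next held 22% and parted the TAC groups. Day-1 TAC replicate 1 correlated least with its own group (mean r = 0.979 across genes). In day-1 TAC replicate 3, Xist had 10532 reads against at most 40 elsewhere, and Ddx3y, a Y-linked gene, had 18 reads against 3312 to 4706. The limma F test called 6092 of 13712 genes among the 3 groups.

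The comparison of day-1 TAC with sham asks how the ventricle differs after pressure load imposed in the first days of life. Among genes with a mean of at least 2 on the log2 scale, large rises were in Nmrk2, a nicotinamide riboside kinase, which was 49.4-fold higher (log2 fold change 5.63, SE 0.35), and in Acta1, the skeletal alpha-actin of striated muscle, which was 34.6-fold higher (5.11, SE 0.35). Nmrk2 lies on chromosome 10 from 81198170 to 81202051, and Acta1 on chromosome 8 from 123891769 to 123894751. The natriuretic peptide genes Nppa and Nppb, classic markers of ventricular wall stress, rose by 2.80 (SE 0.22) and 1.94 (SE 0.21). The water channel gene Aqp4 fell (-3.70), from 7.26 ± 0.29 to 3.56 ± 0.78, and the alcohol dehydrogenase gene Adh1 (-3.48) fell as well.

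Other large rises with day-1 TAC were Dct (4.02), Krt18 (3.63), Cilp (3.38), Adamts20 (3.33), Mgat5b (3.22), Serpinb1c (3.20) and Tceal7 (2.98). Other large falls were Ms4a4d (-3.42), Timp4 (-3.36), Hif3a (-3.23), Scd4 (-3.14), Cenpf (-3.12), Corin (-2.66) and Plekhh1 (-2.62). Adjusted p for these rises and falls was at most 0.00403 for Plekhh1. Plekhh1 (3.66 ± 1.35) and Cenpf (3.59 ± 1.26) varied widely between the day-1 TAC libraries, with replicate 1 at 2.18 and 4.96. Scd4, Cilp and Krt18 had day-1 TAC SDs of 1.05, 1.04 and 1.01. Of the day-1 TAC libraries, replicate 1 lay farthest from sham for Acta1 (11.5 against 10.2 and 10.12) and Nmrk2 (6.96 against 5.32 and 6.12). Replicate 3 did so for Dct, Mgat5b, Tceal7 and Cenpf. Of the pressure-overload and fetal-type cardiomyocyte genes, 12 of 19 rose and none fell (12 rose and 1 fell adjusted over the list alone), including Fhl1 (1.36). Extracellular matrix genes rose in 25 of 34 (30 rose and 1 fell adjusted over the list alone), with Col8a1 at 2.74, Timp1 at 2.08, Col16a1 at 1.28 and Col1a1 at 0.81. Postn, which encodes the matrix protein periostin, rose by 1.27 (SE 0.29, adjusted p = 0.00802). Camera called both lists as higher (adjusted p = 2.86e-06 and 2.14e-11), with adjusted p = 0.155 and 0.373 with an estimated correlation. Among markers of neighbouring tissues, atrial cardiomyocyte markers rose in 1 and fell in 2 of 13 (median -0.12), and skeletal muscle markers rose in 2 and fell in 1 of the 4 tested (median 0.77).

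Fatty acid oxidation genes fell in 24 of 33 and rose in none (25 fell adjusted over the list alone). Ppargc1a, a coactivator of mitochondrial gene expression, fell by 1.02, Eci2 by 0.77 and Acsl1 by 0.70. Cardiac ion channel genes fell in 12 of 21 (13 adjusted over the list alone), among them the potassium channel genes Kcnd2 (-1.25), Kcnj5 (-1.24) and Kcne1 (-0.70) and the calcium channel gene Cacna1g (-0.95). Camera gave adjusted p = 5.25e-08 and 0.00277 for these lists, and 0.373 and 0.485 with an estimated correlation. Heat shock genes rose in 9 of 14 (9 adjusted over the list alone), with Hsph1 at 1.14 and the small heat shock gene Cryab at 0.66 (camera adjusted p = 2.29e-05, and 0.266 with an estimated correlation). Mature sarcomere and calcium-handling genes went both ways, with 2 risen and 8 fallen of 25 (3 and 8 adjusted over the list alone), and the list was not called (adjusted p = 0.253). Myom2 fell by 1.64 and the myosin kinase gene Mylk3 by 1.48, while S100a1 rose by 0.75 and Ckmt2 by 0.47. The main myosin heavy chain genes did not pass the test: Myh6 differed by -0.49 (SE 0.22, adjusted p = 0.117) and Myh7 by -0.45 (SE 0.22, adjusted p = 0.139).

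DNA replication genes rose in 8 of 29 (7 adjusted over the list alone) with day-1 TAC, among them the helicase genes Mcm2 at 1.57 (SE 0.31) and Mcm3 at 1.52 (SE 0.36). Camera called the list (adjusted p = 0.000925, and 0.696 with an estimated correlation), but not without day-1 TAC replicate 1, when its adjusted p was 0.0509. That library also had the highest mean of the mitosis list, 4.04 against 1.25 to 3.07 in the others. Mitosis and cytokinesis genes rose in 1 and fell in 1 of 30, both adjusted over all genes and adjusted over the list alone (camera adjusted p = 0.258). Cenpf fell by 3.12, Cenpa rose by 0.73, and Mki67, a proliferation marker, stood at 0.31 (SE 0.73, adjusted p = 0.77). The cyclin gene Ccnd1 rose by 1.22 (SE 0.29, adjusted p = 0.00902).

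Macrophage markers rose in 5 and fell in 1 of 23 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00277, and 0.645 with an estimated correlation), and the fallen marker was the scavenger receptor gene Cd163 (-1.36). Endothelial cell markers fell in 7 of 23 (7 adjusted over the list alone) and the list was not called (adjusted p = 0.148). Ptprb fell by 0.40, the cadherin gene Cdh5 by 0.28, and Pecam1 stood at -0.16 (SE 0.07, adjusted p = 0.103). Angiogenic and growth factor genes rose in 7 and fell in 5 of 29 (8 and 6 adjusted over the list alone; adjusted p = 0.445). Angpt1, a ligand of the endothelial receptor Tek, fell by 1.34, Pgf by 1.18 and the hypoxia-inducible factor gene Epas1 by 0.59, while Tgfb3 rose by 0.62. Vegfa stood at 0.03 (SE 0.11, adjusted p = 0.864), and the cardiac transcription factor gene Gata4 at 0.21 (SE 0.11, adjusted p = 0.162).

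By the limma test 4776 genes were called with day-1 TAC against sham, 1963 higher and 2813 lower, with 446 and 469 of them at least 2.0-fold changed. The split depends on the scaling: 41.1% of the calls were higher as deposited and 47.6% to 50.6% under 4 other scalings. The groups did not overlap in 47.97% of genes tested, where chance gives 10%. With a minimum fold change of 1.2 in the test, 1428 genes were called.

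**Figure D1:**
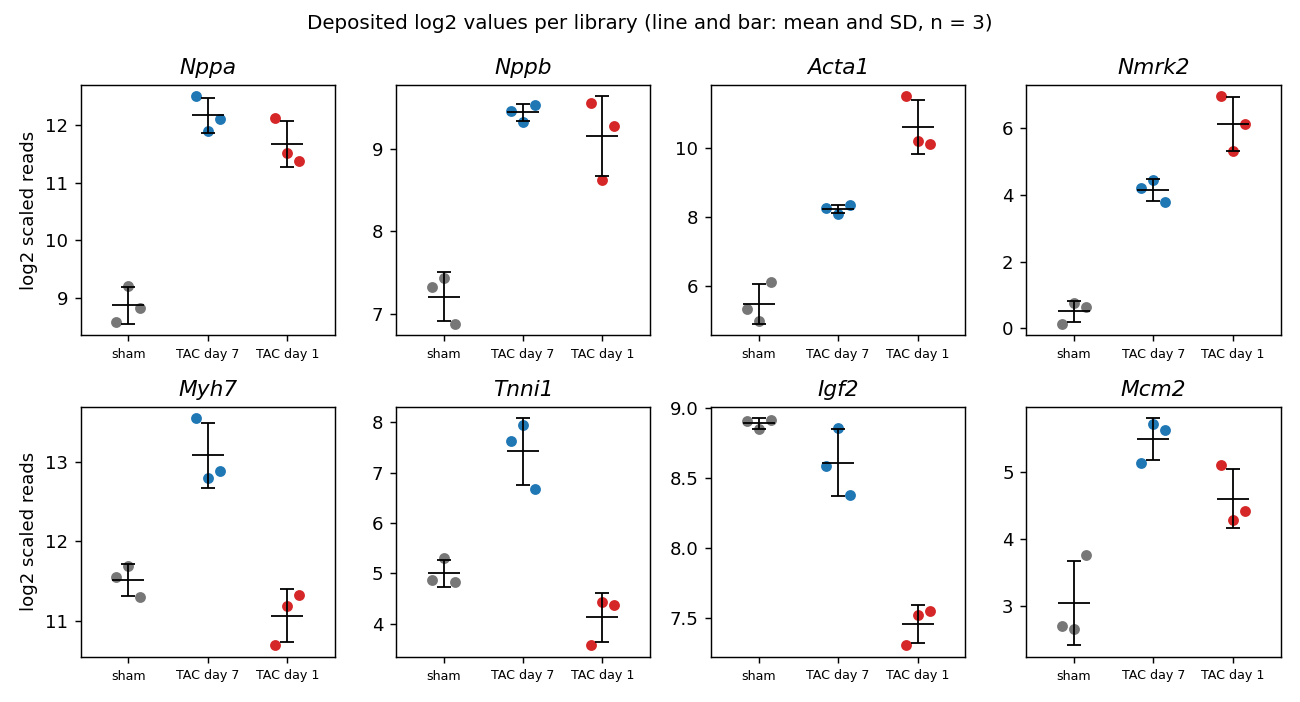
Deposited log2 values of 8 genes in each library (y axis, log2 scaled reads), with the mean and SD of 3 libraries per group. Nppa and Nppb are high in both TAC groups, Acta1 and Nmrk2 are highest with day-1 TAC, Myh7 and Tnni1 are highest with day-7 TAC, and Igf2 is lowest with day-1 TAC (7.46 ± 0.13).

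The comparison of day-7 TAC with sham asks the same of load imposed later. The orphan nuclear receptor gene Nr4a3, on chromosome 4 from 48045153 to 48086447, rose by 4.18 (SE 0.30), from 1.33 ± 0.14 to 5.51 ± 0.36. Nppa rose 9.80-fold (3.29, SE 0.22), Nppb by 2.23 (SE 0.21), and Acta1 by 2.74 (SE 0.35). Myh7, the slow beta-myosin heavy chain of the fetal ventricle, rose by 1.57 (SE 0.22, adjusted p = 0.000848), and Tnni1, the fetal slow troponin I, by 2.42 (SE 0.32). Falls included Ms4a4d (-3.00) and the muscle genes Asb15 (-2.93) and Klhl38 (-2.85).

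Other large rises with day-7 TAC were Krt18 (3.76), the neutrophil gene S100a9 (3.76), Nmrk2 (3.64), Dct (3.48), Adamts20 (3.23), Mgat5b (3.23) and Baiap2l1 (2.84). Baiap2l1 varied widely between the day-7 TAC libraries, at 7.06 ± 1.57 against 4.21 ± 0.34 in sham. Other large falls were Phkg1 (-2.84), Art1 (-2.80), Aqp4 (-2.79), Cenpf (-2.65), Gal3st3 (-2.37), Csdc2 (-2.27) and Gcnt1 (-2.21). Pressure-overload and fetal-type cardiomyocyte genes rose in 15 of 19 (16 rose and 1 fell adjusted over the list alone), including Xirp2 at 2.18 and Fhl1 at 1.30, and camera called the list (adjusted p = 4.11e-09, and 0.0585 with an estimated correlation). Genes high before birth that decline afterwards rose in 9 of 18 (10 rose and 1 fell adjusted over the list alone), among them the growth factor gene Ptn (1.71) and the RNA-binding protein genes Igf2bp3 (1.14) and Igf2bp2 (1.09). Camera gave adjusted p = 0.00414 for this list, and 0.699 with an estimated correlation. Atrial cardiomyocyte markers rose in 1 and fell in 2 of 13 (median -0.35), and skeletal muscle markers rose in 3 and fell in 1 of 4 (median 1.33). Only these 4 of the 13 skeletal muscle markers in the table passed the filter. Of them Myh8 passed through the TAC libraries, with 6 to 11 reads in sham. Among those left out, the mean linear value went from 0.509 to 0.691 for Mylpf and from 0.835 to 0.513 for Myh4. Skeletal muscle tissue in the day-7 TAC libraries was not tested.

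Nuclear genes of oxidative phosphorylation fell in 21 of 45 and rose in none (23 fell adjusted over the list alone), with Cox7a1 at -0.68, Atp5j at -0.41, Ndufs7 at -0.39 and Ndufa4 at -0.39. Fatty acid oxidation genes fell in 22 and rose in 2 of 33 (24 and 2 adjusted over the list alone). Acadm fell by 0.59, Etfdh by 0.56, Eci2 by 0.53 and Etfa by 0.45, while Ppargc1a, which fell with day-1 TAC, rose by 0.78 (adjusted p = 0.00345). Camera called both lists as lower (adjusted p = 1.23e-06 and 9.45e-06, and 0.724 and 0.699 with an estimated correlation). Mature sarcomere and calcium-handling genes fell in 8 of 25 (2 rose and 10 fell adjusted over the list alone), with Mylk3 at -1.26 and the calcium store genes Hrc at -0.73 and Trdn at -0.52 (camera adjusted p = 0.00813, and 0.699 with an estimated correlation). Myh6 stood at -0.35 (SE 0.22, adjusted p = 0.273). Cardiac ion channel genes fell in 9 and rose in 1 of 21 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00532, and 0.699 with an estimated correlation). Kcnj3 fell by 1.77 and Kcnd2 by 1.12, and the gene that rose was Kcne1, by 0.77.

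Extracellular matrix genes rose in 12 of 34 with day-7 TAC (17 adjusted over the list alone; camera adjusted p = 2.82e-05, and 0.699 with an estimated correlation). Spp1, which encodes osteopontin, rose by 3.75 (SE 0.61), Ltbp2 by 2.0, Timp1 by 1.41 and Thbs1 by 1.23. Spp1 had 3 to 5 reads in sham and 16 to 151 with day-7 TAC, so it passed the filter on low values through the TAC libraries. Col1a1 stood at 0.21 (SE 0.18, adjusted p = 0.414). Postn rose by 1.15 (SE 0.29, adjusted p = 0.0154). It stayed higher but lost its call without sham replicate 1 (1.07, adjusted p = 0.0522) or sham replicate 2 (1.03, adjusted p = 0.0576). Of the neutrophil and lymphocyte markers in the table, 9 of 21 passed the filter and 6 of these rose (6 adjusted over the list alone), among them the neutrophil granule genes Ngp (4.87), Ltf (4.65), Retnlg (4.37) and Mmp8 (3.24). With sham means of -1.84, -2.18, -2.98 and -2.56, these 4 passed it through the TAC libraries, so the count leaves out members that stayed low. These rest on few reads: Ngp had 137 to 212 with day-7 TAC and 3 to 9 in sham. Camera gave adjusted p = 4.2e-05 for the list, 0.000146 with no filter, and 0.699 with an estimated correlation.

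DNA replication genes rose in 6 of 29 (6 adjusted over the list alone), with Mcm2 at 2.45, Mcm5 at 2.09, Mcm3 at 1.84 and the primase gene Prim1 at 1.5 (camera adjusted p = 5.57e-05, and 0.724 with an estimated correlation). Mitosis and cytokinesis genes rose in 1 and fell in 1 of 30 (1 and 1 adjusted over the list alone; adjusted p = 0.509): Cenpa rose by 1.03 and Cenpf fell by 2.65, while Mki67 stood at -0.64 (SE 0.73, adjusted p = 0.542) and Ccnd1 at 0.79 (SE 0.29, adjusted p = 0.0639). Endothelial cell markers fell in 4 and rose in 1 of 23 (4 and 1 adjusted over the list alone; adjusted p = 0.303), with Cldn5 at -0.56 and Cdh5 at -0.33. Of the fallen markers, Tek lost its call in 3 of 9 limma fits with a library left out (adjusted p up to 0.0749). Tspan7 lost it in 5 (up to 0.0949). Pecam1 stood at -0.08 (SE 0.07, adjusted p = 0.422) and Vegfa at 0.07 (SE 0.11, adjusted p = 0.655). Gata4 rose by 0.37 (SE 0.11, adjusted p = 0.0296). That call was lost without sham replicate 1, sham replicate 3, day-7 TAC replicate 1 or day-7 TAC replicate 2, with log2 fold changes of 0.28 to 0.39 and adjusted p of 0.0633 to 0.105.

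**Figure D2:**
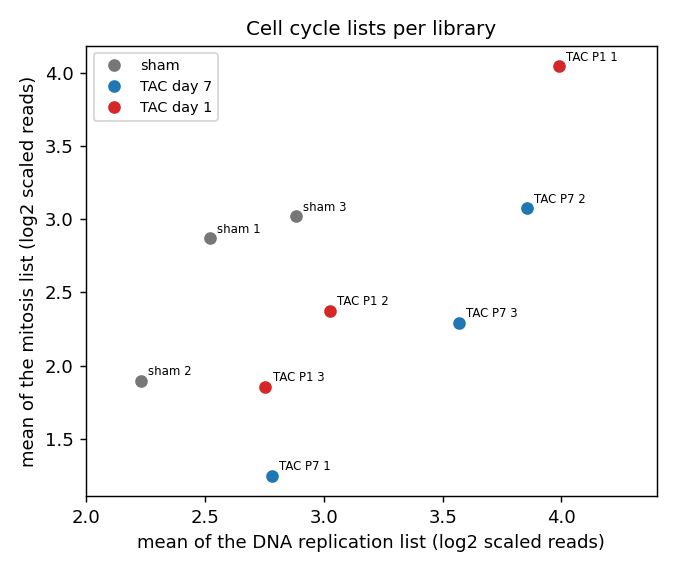
Mean log2 value of the mitosis list (y axis) against that of the DNA replication list (x axis) in each of the 9 libraries, coloured by group. The replication mean was 2.54 ± 0.33 in sham, 3.40 ± 0.56 with day-7 TAC and 3.26 ± 0.65 with day-1 TAC, and the mitosis mean 2.6 ± 0.61, 2.21 ± 0.92 and 2.76 ± 1.14.

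The limma test called 3962 genes with day-7 TAC against sham, 1889 higher and 2073 lower, of which 341 and 342 were at least 2.0-fold changed. Of the calls 47.7% were higher, and 48.3% to 51.3% under the other scalings. Groups did not overlap in 46.74% of genes, where chance gives 10%. With a minimum fold change of 1.2, 1066 genes were called, and without day-7 TAC replicate 2, 2594.

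**Figure D3:**
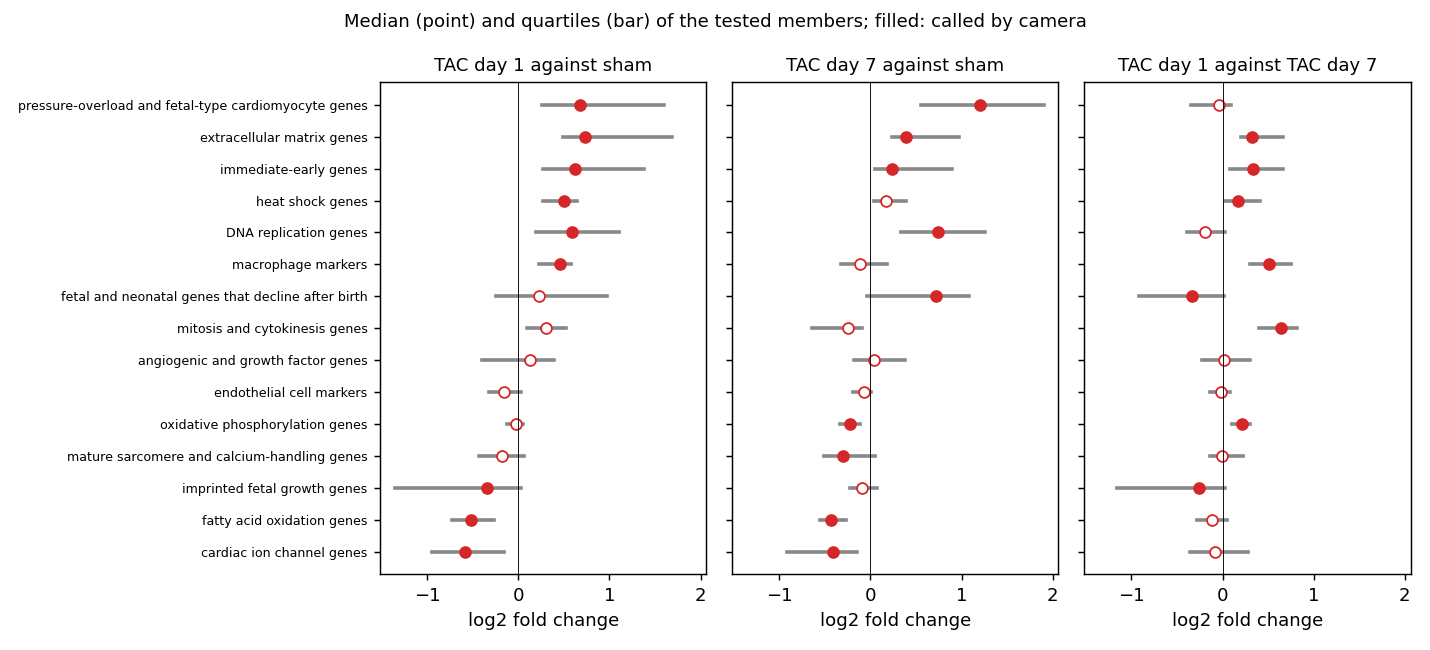
Log2 fold changes (x axis) of 15 gene lists in the 3 comparisons, with a point at the median of the tested members, a bar from the lower to the upper quartile, and a filled point where camera called the list at the preset correlation. Extracellular matrix genes are called as higher in each comparison (medians 0.73, 0.39 and 0.33; adjusted p = 0.373, 0.699 and 0.57 with an estimated correlation), and endothelial cell markers in none.

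The direct comparison of the TAC groups asks whether the hearts differ with the age at surgery. The time under load differed as well, since all hearts were taken at day 14. The lipase gene Pnpla3 was 7.29-fold higher with day-1 TAC (log2 fold change 2.86, SE 0.28). Muscle genes that were higher included Acta1 at 2.37 (SE 0.35), the myosin light chain gene Myl1 at 2.34 and Nmrk2 at 1.98. Tnni1, on chromosome 1 from 135779434 to 135810989, was lower (-3.29, 4.13 ± 0.49 against 7.42 ± 0.67), as was Myh7, on chromosome 14 from 54970684 to 54994626 (-2.01, 11.07 ± 0.33 against 13.08 ± 0.41). Nppa and Nppb did not pass the test between the TAC groups, at -0.50 (SE 0.22, adjusted p = 0.148) and -0.28 (SE 0.21, adjusted p = 0.386).

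Also higher with day-1 than with day-7 TAC were Lrtm1 (2.55), Cacna2d3 (2.40), Art1 (2.25), Hrasls (2.19) and Lrrc55 (2.05), with Art1 below sham in both TAC groups. Lower were Scd4 (-2.70), Nr4a3 (-2.60), Atf3 (-2.07), Abca4 (-2.03), Corin (-1.90), Timp4 (-1.86) and Ppargc1a (-1.80). Oxidative phosphorylation genes were higher in 14 of 45 and lower in none (22 adjusted over the list alone), with Cox7a1 at 0.70, Cycs at 0.65 and Ndufs7 at 0.37 (camera adjusted p = 6.44e-08, and 0.602 with an estimated correlation). Imprinted fetal growth genes were lower in 9 of 17 (9 adjusted over the list alone), with Plagl1 at -1.71, H19 at -1.40, the insulin-like growth factor gene Igf2 at -1.16 and Slc38a4 at -0.65 (camera adjusted p = 0.0034, and 0.424 with an estimated correlation).

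Macrophage markers were higher in 7 of 23 with day-1 against day-7 TAC (7 adjusted over the list alone), with F13a1 at 1.31, Cd68 at 1.10, Mrc1 at 0.93 and the complement gene C1qa at 0.76 (camera adjusted p = 1.6e-06, and 0.57 with an estimated correlation). With day-7 TAC these genes lay below sham, F13a1 at -1.14, Cd68 at -0.66, Mrc1 at -0.55 and C1qa at -0.22, and with day-1 TAC F13a1 lay 0.17 above it. Of the markers 1 rose and 4 fell with day-7 TAC against sham (1 and 3 adjusted over the list alone; adjusted p = 0.398). Extracellular matrix genes were higher in 6 and lower in 1 of 34 (6 and 1 adjusted over the list alone; camera adjusted p = 6.68e-06, and 0.57 with an estimated correlation), with Col8a1 at 1.74. Col1a1 was higher by 0.60 (SE 0.18, adjusted p = 0.0421). That call was lost without sham replicate 1, any of the 3 day-7 TAC libraries, or day-1 TAC replicate 1 or 2, with log2 fold changes of 0.51 to 0.67 and adjusted p of 0.052 to 0.123. Camera called mitosis and cytokinesis genes as higher (adjusted p = 0.0246, and 0.751 with an estimated correlation), although 0 of 30 members passed the limma test, adjusted over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Without day-7 TAC replicate 1 or day-1 TAC replicate 1 that list was not called, with an adjusted p of up to 0.993, nor was it under quantile normalization, median centring, trimmed-mean or median-ratio scaling (0.054 to 0.0934). Mki67 stood at 0.95 (SE 0.73, adjusted p = 0.397), with 2925 reads in day-1 TAC replicate 1 and 243 in day-7 TAC replicate 1.

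Endothelial cell markers were lower in 2 of 23 (2 adjusted over the list alone; camera adjusted p = 0.799), Sox17 at -0.71 and Ptprb at -0.42, and the median of the list was -0.01 as deposited and 0.01 to 0.04 under every other scaling. Angiogenic and growth factor genes were higher in 5 and lower in 4 of 29 (6 and 4 adjusted over the list alone; adjusted p = 0.323). Angpt1 was higher by 0.68, Igf1 by 0.66 and Fgf1 by 0.46, with Angpt1 and Fgf1 below sham in both TAC groups, and Nov was lower, at -1.47. Nerve, Schwann cell and neurotrophin genes were higher in 3 and lower in 1 of 18 (3 and 1 adjusted over the list alone; adjusted p = 0.13). The lower gene was Dbh, which encodes the enzyme that makes noradrenaline, at -1.14 (SE 0.26, adjusted p = 0.0161), and without day-7 TAC replicate 1 it was -1.10 with an adjusted p of 0.0525. Of the remaining genes fixed for report, Myh6 stood at -0.14 (adjusted p = 0.703), Gata4 at -0.16 (0.347), Postn at 0.12 (0.803), Vegfa at -0.04 (0.815), Pecam1 at -0.08 (0.467) and Ccnd1 at 0.43 (0.324).

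The limma test called 2287 genes between the TAC groups, 880 higher with day-1 TAC and 1407 lower, of which 176 and 169 were at least 2.0-fold changed. Of these calls 38.5% were higher as deposited, and 46.1% to 48.5% under the other scalings. The count fell to 1290, 1261 and 1300 without day-7 TAC replicate 1, 2 or 3, and to 273 with a minimum fold change of 1.2.

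**Figure D4:**
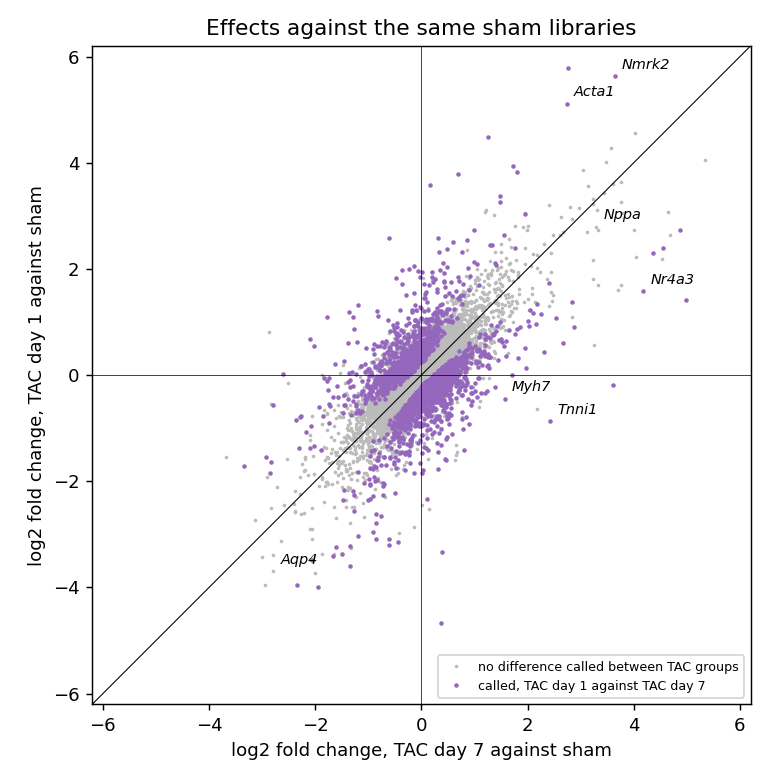
Log2 fold change of each of 13712 genes with day-1 TAC (y axis) against that with day-7 TAC (x axis), both against the same sham libraries, with the line of equal change. The 2287 genes called between the TAC groups are purple, and Acta1 and Nmrk2 lie above the line while Nr4a3, Tnni1 and Myh7 lie below it.

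Across genes, the fold changes of the TAC groups against the shared sham libraries correlated with Pearson's r = 0.718 and Spearman's rho = 0.662, where simulation without effects gave 0.50 and 0.46. Genes are not independent replicates. The covariance was 0.230 against 0.0204 simulated, a difference of 0.210. Genes such as Nppa, Krt18 and Dct were among 991 higher in both comparisons, and Aqp4, Ms4a4d and Cenpf among 1374 lower in both. Independent calls would give 270.4 and 425.3. In opposite directions, 18 genes were called higher with day-1 and lower with day-7 TAC, and 20 the reverse, where independent calls would give 296.8 and 387.5. The shared sham libraries by themselves raise the counts in the same direction and lower those in opposite directions. With 3 sham libraries the controls could not be split between the comparisons, and the excess over the simulation is not free of the shared controls. In 1098 genes day-1 TAC differed from both other groups in the same direction, and in 821 genes day-7 TAC did.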

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

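Tests of the library with Xist reads, of skeletal muscle tissue, of other actin genes, of a shared batch and of other splits of the samples were chosen after the results were seen, and the correction for GC content and gene length was added after the data were seen. What singles out the results here is the limma test between the TAC groups, which is the test of the difference between their effects against the same sham libraries. It called 2287 genes, 39 of the genes described as higher with day-1 TAC, 29 as lower, and 14 gene lists by camera at the preset correlation. With an estimated correlation it called 0 of 33 lists (lowest adjusted p 0.424). Higher and lower here compare day-1 with day-7 TAC. Of the genes named as higher, Angpt1, Art1, Asb15, Csdc2, Fgf1, Gal3st3, Gfra3, Hrc, Klhl38 and Ndufs7 lay below sham in both TAC groups, less so with day-1 TAC. Of those named as lower, Atf3, Igf2bp3, Ngp, Nr4a3 and Retnlg lay above sham in both.

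Among the higher genes that the naming rule gave were muscle genes: Acta1 (2.37), Myl1 (2.34), Asb15 (1.39), Klhl38 (1.01), Ckmt2 (1.08), Hrc (0.52) and S100a1 (0.47), together with Art1 (2.25) and Nmrk2 (1.98). Heat shock genes were Hsph1 (0.86), Cryab (0.67), Hspb8 (0.51) and Hspa4l (0.44). Genes of metabolism and respiration were Pnpla3 (2.86), Hrasls (2.19), Cox7a1 (0.70), Cycs (0.65) and Ndufs7 (0.37). Also higher with day-1 than with day-7 TAC were Lrtm1 (2.55), Cacna2d3 (2.40), Lrrc55 (2.05), Gal3st3 (1.53) and Csdc2 (1.5).

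Matrix, immune and growth factor genes in the higher group were Cilp (1.90), Col8a1 (1.74), Col6a3 (0.68), Timp1 (0.67) and Col1a1 (0.60); F13a1 (1.31), Cd68 (1.10), Mrc1 (0.93), C1qa (0.76) and C1qb (0.72); Angpt1 (0.68), Igf1 (0.66) and Fgf1 (0.46). Nerve and neurotrophin genes were Bdnf (1.28), Gfra3 (0.88) and Uchl1 (0.80). Several of these calls lie near the threshold and were lost with a library left out, while the genes stayed higher. Without day-7 TAC replicate 2, Cilp was at 1.65 (adjusted p = 0.0693) and Col6a3 at 0.64 (0.0526). The call of Col1a1 was lost without sham replicate 1, each day-7 TAC library, or day-1 TAC replicate 1 or 2 (log2 fold change 0.51 to 0.67, adjusted p 0.052 to 0.123). That of Bdnf was lost without day-7 TAC replicate 1 or 2, or day-1 TAC replicate 1 or 3 (1.03 to 1.21, adjusted p 0.071 to 0.0831). Gfra3 lost its call without sham replicate 2, day-7 TAC replicate 1 or 2, or any day-1 TAC library (0.72 to 0.95, adjusted p 0.0528 to 0.107). Uchl1 lost it without sham replicate 2 or 3, day-7 TAC replicate 2 or 3, or day-1 TAC replicate 1 or 3 (0.65 to 0.80, adjusted p 0.0517 to 0.125).

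The lower group held the slow and fetal contractile genes Tnni1 (-3.29) and Myh7 (-2.01), and Myom2 (-1.13). It held the fetal growth genes Plagl1 (-1.71), H19 (-1.40), Igf2 (-1.16), Igf2bp2 (-1.14), Igf2bp3 (-0.95) and Slc38a4 (-0.65). Metabolic genes in it were Scd4 (-2.70), Ppargc1a (-1.80) and Adh1 (-1.42). Stress and hypoxia-related genes were Nr4a3 (-2.60), Atf3 (-2.07), Hif3a (-1.63) and Epas1 (-0.41). Nr4a3 and Atf3 were the 2 immediate-early genes called as lower, while 6 of the 21 in that list were called as higher. Endothelial, growth factor and immune genes were Sox17 (-0.71), Ptprb (-0.42), Nov (-1.47), Pgf (-0.77), Ngp (-2.14) and Retnlg (-2.07). The rest were Abca4 (-2.03), Corin (-1.90), Timp4 (-1.86), Plekhh1 (-1.76), Kcne1 (-1.46), Dbh (-1.14) and Ctgf (-1.07). Without day-7 TAC replicate 1 Dbh was at -1.10 (adjusted p = 0.0525). Ctgf lost its call without sham replicate 2, any day-7 TAC library, or day-1 TAC replicate 2 or 3 (log2 fold change -1.24 to -0.75, adjusted p 0.0551 to 0.119).

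Among lists, the median log2 fold change was 0.64 for mitosis and cytokinesis genes, 0.33 for extracellular matrix genes, 0.51 for macrophage markers, 0.95 for erythroid markers, 0.21 for oxidative phosphorylation genes and 0.17 for glycolysis genes. It was 0.37 for interferon-response genes, 0.34 for immediate-early genes, 0.25 for stress response genes and 0.17 for heat shock genes. Medians were negative for neutrophil and lymphocyte markers (-1.57), circadian clock genes (-0.32), imprinted fetal growth genes (-0.26) and fetal and neonatal genes (-0.33). With an estimated correlation 2 of 33 lists had an unadjusted p under 0.05, and none an adjusted p under it (lowest 0.424).

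The first pattern is day-1 TAC replicate 3, with 10532 reads of Xist and 18 of Ddx3y where the other libraries had at most 40 and at least 3312. On autosomal genes called without it, it lay at 0.81 of the way from sham to the other day-1 TAC libraries, and at 0.703 of the way from day-7 TAC, which argues against a library from another group of the series. Without it 79.2% of the calls of day-1 TAC against sham returned, so it does not account for most of them. In this library the Y-linked genes Eif2s3y, Kdm5d and Uty had 22, 3 and 5 reads, against at least 3119, 655 and 1161 elsewhere. With the Xist reads, these values argue against a sample from a male mouse. The labels give no sex. A female sample would leave the groups unequal in sex, and no fit had sex as a covariate.

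The second pattern is the difference between the TAC groups. After each library was corrected for trends on GC content and length, 84.6% of the calls were kept, which argues against such a trend as the main cause. Genes whose span overlaps another gene were called no more often than others (odds ratio 0.926, interval at 95% 0.843 to 1.016). The span held introns and ignored strand, so genes without shared exons could be among the 5712 counted as overlapping. The values therefore cannot decide on another counting rule for overlapping genes in the day-1 TAC libraries. A batch shared by the day-1 TAC libraries cannot be told apart from the group, because the labels name no batch. The crossed rows described above are what a join of separate day-1 TAC values would give, so both comparisons with day-1 TAC carry this limit. The 1098 genes in which day-1 TAC stood apart from both other groups decide nothing. Age at surgery and time under load stay open as well, and neither was tested.

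The third pattern is the gain of Acta1 with day-1 TAC, from a mean linear value of 47.5 in sham to 1730. The skeletal muscle list was not called (adjusted p = 0.148); of its members Mybpc2 gained most, 5.57% of the gain of Acta1, while Tnni2 went from 4.38 to 1.89 and the abundant fast-fibre transcript Mylpf from 0.509 to 0.608. Skeletal muscle tissue brings all its abundant transcripts, so these values argue against it as the source. A fixed share of reads from other actin genes is argued against too, since Actc1 rose most of them, by 0.891 (SE 0.175), and Acta1 by 5.11 (SE 0.351). A share that differs in the day-1 TAC libraries stays open for them. Expression of Acta1 by heart muscle cells stays open as well and was not tested. Acta1 was in the list of pressure-overload and fetal-type cardiomyocyte genes fixed before the data were examined.

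For each pair of groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05; the real splits called 4776, 3962 and 2287 genes and the highest other split 1 gene in each case. Across the 3 groups 1 of 100 splits drawn from 280 possible, the real one, gave as many as 6092 genes by the F test, and the highest other gave 353. An arbitrary split of these libraries would thus seldom give that count. The splits cannot tell the surgery from a batch or litter that follows the groups.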

How the results depend on the processing

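The trimmed-mean and median-ratio scalings, voom weights, the fits without genes on chromosomes X and Y, the correction for GC content and length and camera under other filters and scalings were chosen after seeing the data. Apart from the settings named next, 17 settings gave 4017 to 5010 genes for day-1 TAC against sham, 3335 to 4919 for day-7 TAC against sham and 1732 to 2791 between the TAC groups, all within 1.5 times the counts reported. By construction, a minimum fold change of 1.2 gave fewer: 1428, 1066 and 273. The replicate number as a block with TAC libraries alone gave 1167 between the TAC groups, in a fit with fewer samples; same numbers did not resemble each other (r across genes -0.195, -0.107 and -0.024), so they pair nothing. Camera with an estimated correlation called 0, 0 and 0 lists. At the preset correlation, camera called 12 lists, not 14, between the TAC groups under each of 4 other scalings and both other filters. Leaving out each library in turn gave 3259 to 4525, 2594 to 4404 and 1261 to 2491 genes, 13 to 17, 10 to 13 and 11 to 15 lists, and 4473 to 5476 genes by the F test. The lowest gene counts came without sham replicate 2 for day-1 TAC and for the F test, and without day-7 TAC replicate 2 otherwise. The correlation of effects was 0.681 to 0.756 over 22 settings.

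Of 1789, 1839 and 1672 values of the genes that the naming rule gave under alternatives, 1748, 1800 and 1600 kept direction and side of the threshold, 31, 32 and 65 lost a call and 4, 3 and 1 gained one. The rest changed sign or became 0, all in results that were not called. Quantile normalization gave Myh6 0 in each comparison, because it is the highest gene of every library and is set equal by construction, and Pecam1 0.015 between the TAC groups. With library weights Vegfa was -0.006 for day-1 TAC against sham and Postn -0.093 between the TAC groups. With libraries left out, the log2 fold changes with day-1 TAC were -0.07 to 0.112 for Vegfa, -0.387 to 0.826 for Mki67 and -0.576 to -0.304 for Myh6. With day-7 TAC they were -0.028 to 0.154 for Vegfa, -1.28 to 0.084 for Mki67, -0.005 to 0.397 for Col1a1 and -0.373 to -0.298 for Myh6. Between the TAC groups they were -0.11 to 0.003 for Vegfa, -0.231 to 0.041 for Myh6, -0.288 to 0.377 for Postn and -0.111 to -0.023 for Pecam1. The cause of these changes was not tested. A count model, planned only for raw counts, was not run on the recovered reads, although voom weights were. Depth limits genes with few reads, such as Spp1 and those of neutrophils.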

Other observations

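The test of DNA replication against mitosis genes was chosen after the result was seen. Immediate-early genes, which respond to signals within the hour, rose in 13 of 21 with day-1 TAC against sham (13 adjusted over the list alone; camera adjusted p = 1.6e-06, and 0.155 with an estimated correlation). With day-7 TAC 7 rose and 2 fell (8 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00673 for day-7 TAC, and 0.699 with an estimated correlation. Between the TAC groups 6 were higher and 2, Nr4a3 and Atf3, were lower (9 and 2 adjusted over the list alone). For that comparison camera gave adjusted p = 0.0034, and 0.424 with an estimated correlation. Inflammatory and gp130 cytokine genes rose in 7 of 17 with day-1 TAC and in 6 with day-7 TAC (7 and 6 adjusted over the list alone; adjusted p = 0.00202 and 0.0313, and 0.373 and 0.699 with an estimated correlation). The day-7 call was lost without sham replicate 1 or day-7 TAC replicate 1, with an adjusted p of up to 0.105. Neutrophil and lymphocyte markers, of which 9 of 21 in the table passed the filter, rose in 5 with day-1 TAC (6 adjusted over the list alone; adjusted p = 0.00277, and 0.373 with an estimated correlation), and 2 were lower with day-1 than with day-7 TAC (6 adjusted over the list alone; adjusted p = 0.0254, and 0.57 with an estimated correlation), a call lost without day-7 TAC replicate 2 or day-1 TAC replicate 2, with up to 0.0856, and with no filter or the stricter filter (0.0696 and 0.163).

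Cardiac transcription factor and regeneration-regulator genes fell in 14 and rose in 5 of 31 with day-1 TAC (17 and 5 adjusted over the list alone; adjusted p = 0.0131, and 0.373 with an estimated correlation). With day-7 TAC 12 fell and 4 rose (15 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.133). Glycolysis and glucose uptake genes rose in 8 and fell in 4 of 22 with day-1 TAC (9 and 4 adjusted over the list alone; adjusted p = 0.0145, and 0.338 with an estimated correlation). Between the TAC groups 9 were higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.0228, and 0.424 with an estimated correlation), a call lost without day-1 TAC replicate 3 (0.0575). Genes of the unfolded protein and integrated stress response rose in 6 and fell in 2 of 22 with day-1 TAC (7 and 2 adjusted over the list alone; adjusted p = 0.0201, and 0.393 with an estimated correlation), a call lost without sham replicate 1 (0.0576) and with the stricter filter (0.0978). Between the TAC groups 6 were higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.0034, and 0.424 with an estimated correlation).

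Imprinted fetal growth genes fell in 8 and rose in 1 of 17 with day-1 TAC against sham (8 and 1 adjusted over the list alone; adjusted p = 0.026, and 0.338 with an estimated correlation), a call lost without day-1 TAC replicate 2 (0.055) and with the stricter filter (0.0594). Glucocorticoid-responsive genes fell in 7 of 16 (7 adjusted over the list alone; adjusted p = 0.0162, and 0.667 with an estimated correlation), a call lost without sham replicate 1 or day-1 TAC replicate 2, with up to 0.147. Between the TAC groups, circadian clock genes were lower in 5 and higher in 1 of 19 (7 and 1 adjusted over the list alone; adjusted p = 0.0362, and 0.424 with an estimated correlation), and fetal and neonatal genes lower in 6 and higher in 1 of 18 (6 and 1 adjusted over the list alone; adjusted p = 0.0183, and 0.57 with an estimated correlation). Without day-1 TAC replicate 3 neither was called (0.0765 and 0.0584). Heat shock genes were higher in 5 of 14 and interferon-response genes in 2 of 21 (5 and 1 adjusted over the list alone; adjusted p = 0.0034 and 0.00298, and 0.424 and 0.57 with an estimated correlation). Of 5 erythroid markers 1 was higher (1 adjusted over the list alone; adjusted p = 0.0421, and 0.57 with an estimated correlation), a call lost without day-7 TAC replicate 1 or day-1 TAC replicate 3, with up to 0.182, and in 6 of 9 other fits, which were both other filters and 4 other scalings (0.0644 to 0.163).

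Lists that camera called in none of the comparisons included fibroblast identity markers, of which 6 rose and 5 fell of 18 with day-1 TAC and 4 rose and 3 fell with day-7 TAC (7 and 5, and 4 and 3, adjusted over the list alone). Smooth muscle and pericyte markers rose in 3 and fell in 5 of 17 with day-1 TAC (4 and 7 adjusted over the list alone), where the median was 0.09 and the mean -0.04. YAP/TEAD target genes rose in 6 and fell in 5 of 22 with day-1 TAC and rose in 6 and fell in 3 with day-7 TAC (6 and 8, and 7 and 4, adjusted over the list alone). Epicardial and mesothelial markers rose in 2 and fell in 1 of 5 with each TAC (2 and 1 adjusted over the list alone), and 1 of 5 adipocyte markers fell in each (0 adjusted over the list alone by limma). Nerve, Schwann cell and neurotrophin genes rose in 6 and fell in 4 of 18 with day-1 TAC and rose in 1 and fell in 5 with day-7 TAC (6 and 4, and 1 and 5, adjusted over the list alone). In that list median and mean differed in sign, -0.08 and 0.05 with day-1 TAC and 0.09 and -0.15 with day-7 TAC. Oxidative phosphorylation genes fell in 6 and rose in 2 of 45 with day-1 TAC against sham (2 and 1 adjusted over the list alone; adjusted p = 0.856), with a median of -0.03 as deposited that turned positive, 0.01 to 0.08, under every other scaling.

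Camera called the DNA replication list in both TAC groups against sham, where 8 and 6 of 29 members rose, and the mitosis list in neither (replication adjusted p = 0.696 and 0.724 with an estimated correlation, and 0.0509 for day-1 TAC without its replicate 1). A candidate explanation is a change in the share of cells in S phase that does not go with the share in mitosis. The mean of the replication list minus that of the mitosis list was 0.85 ± 0.55 in the 6 TAC libraries and -0.05 ± 0.35 in the 3 sham libraries. The difference of 0.90 had an exact two-sided permutation p of 0.0595 over 84 splits, where the smallest possible p is 0.0119. That p pools both TAC groups. Per library, replication minus mitosis was 1.534, 0.78 and 1.275 with day-7 TAC, each above all sham libraries (-0.35, 0.333 and -0.139). With day-1 TAC it was -0.054, 0.65 and 0.898, and replicate 1, the first of these, lay inside the range of the sham libraries. This leaves a change in the share of cycling cells, which would move both lists together, neither excluded nor shown.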
